A study of Mus musculus with 32 samples.

How the data were processed

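The series holds 32 mouse RNA-seq libraries of FACS-sorted CD4 T cells. Tregs and exTregs were compared in 2 experiments and 2 genotypes. Regulatory T cells (Tregs) carried a fluorescent Foxp3-linked reporter and secreted no IL-17, and exTregs lacked the reporter and secreted IL-17. The name exTreg is that of the labels. The sample titles and the stains listed below name no marker of past Foxp3 expression. That in vivo exTregs once carried the reporter was therefore not tested here, and other reporter-negative cells that secrete IL-17 could enter that gate. In the in vivo experiment both came from pooled spleen and lymph nodes of SKG mice, a strain that develops autoimmune arthritis, and in the in vitro experiment sorted Tregs were cultured for 72 h with 50 ng/mL IL-6 and beads coated with antibodies to CD3 and CD28, per the labels' protocols. Before sorting, all cells were stimulated for 3 h with 10 ng/mL PMA and 1 ug/mL ionomycin and stained for secreted IL-17, CD4, the beta chain of the T cell receptor, CD8, CD19 and viability, per the labels' protocols. The labels give 1 floxed allele, written without the number of the gene and read as Ptpn2, and no Cre recombinase for the in vivo Het mice, and a Ptpn2+/- genotype for the in vitro Het cells, each against a wild-type (WT) group. The in vivo strain label is B6.H2d.SKG. The in vitro strain label names a BALB/c Foxp3-eGFP background, while the growth protocol names Foxp3-eGFP SKG mice for these cells, so whether the strain differs is unclear. The in vitro libraries form library set 2 and all carry the Foxp3-eGFP reporter. The in vivo libraries form sets 1 and 3, with batches 20085 and 20086 sorted on a reporter labelled FoxP3 and the other batches on YFP. Reporter and library set therefore differ between the experiments and also vary within the in vivo one.

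Libraries were made from 5 ng of total RNA by Smart-seq2 amplification and Nextera XT tagmentation, a preparation that keeps no strand information, and were sequenced as 50-bp single-end reads, per the labels' protocols. The submitters' processing notes name Bowtie 1.0.0, TopHat 1.4.1, HTSeq 0.7.1 and the genome build mm10, with no order or options. The annotation, the strand setting and the rule for reads that map to several places are not given in the sources used here. The values analysed are the whole-number read counts per gene symbol that the authors deposited, 1 column per library, with no normalization and no pooling of replicates. The table held 23336 gene symbols, of which 20756 were current RefSeq symbols, 2359 were older synonyms and 221 were not matched. 1 line without a gene name held at most 0.000157% of a library's counts and was left out. Totals ran from 5214378 to 12364409 counts per library. Amplified reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

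Groups were taken from the labels for experiment, cell type and genotype. They hold 4 WT and 6 Het libraries each of in vivo Tregs and exTregs, and 3 WT and 3 Het libraries each of cultured Tregs and exTregs. The replicate is the batch number in the labels. In vivo each number covers the Treg and the exTreg library of 1 genotype, and in vitro each number covers all 4 groups. The labels do not say that a batch is an animal, so the p-values measure the spread between these samples, which may be partly technical. The numbers pair the libraries because the labels call them a batch. The correlation of same-numbered libraries' deviations from their group means was 0.057 to 0.177 over 10 in vivo pairs (median 0.1225) and -0.164 to 0.272 over 18 in vitro pairs (median 0.138). No pair of libraries within a group agreed within sampling noise, since the lowest chi-square per degree of freedom was 5.96 over 54 pairs.

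Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter by group with a minimum count of 10, a model with 1 mean per group, and the quasi-likelihood F test with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. The 20 in vivo libraries were fitted together (10624 genes tested), as were the 12 in vitro libraries (10760 genes), and all 32 were fitted together for the difference between the experiments (11496 genes). In each experiment the exTreg contrast averaged both genotypes, the genotype contrasts were made within each cell type, and the interaction was the difference of the genotype contrasts. CPM values, counts scaled by the TMM library sizes, are given as mean ± SD. A log2 fold change is given with its standard error (SE). SEs come from the fold change and the F statistic of the same test. Steps were tested on simulated counts in which 200 genes were changed. At a simulated log2 change of 1 the test recovered 60% of the changed genes for the in vivo exTreg contrast and 60% for the in vitro one. At that size it recovered 46% for the in vivo Treg genotype contrast and 38% for the in vivo exTreg one, and 27% and 30% for the in vitro Treg and exTreg ones. At a log2 change of 2 it recovered 88% and 91% for the exTreg contrasts, 79% and 76% for the in vivo genotype contrasts, and 86% and 79% for the in vitro ones. The simulation gave all groups of an experiment 1 shared spread per gene. The real biological coefficient of variation in vivo was 0.24 and 0.18 in Het and WT Tregs and 0.57 and 0.55 in Het and WT exTregs. The recovery rates of the in vivo genotype contrasts therefore do not hold for either cell type at its own spread.

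Gene lists, named genes, tests and alternatives were fixed before the data were examined, except where stated. 26 lists were fixed, covering T cell programs, signalling and activation, metabolism, the cell cycle, apoptosis and stress, and markers of other cells that the gate might hold. Of their 361 genes, 346 were found in the table, 9 of them under an older symbol. For example Folr4 is the older symbol of Izumo1r. For each list, members past the test were counted over all genes tested and adjusted over the list alone. Lists were also tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The named genes followed a rule. For the exTreg contrasts it took the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 4 and the same sign in every same-batch pair. For genotype, interaction and between-experiment contrasts it took the 5 highest and 5 lowest among called genes with an average log2 CPM of at least 2, or, where none passed, the 3 at that level with the smallest p, so genes of lower level with a smaller p were not named. Predicted genes and antigen receptor segments were not named. Ptpn2, Foxp3 and Il17a were named everywhere, and Il17f, Il22, Il21, Rorc, Il23r, Ccr6, Il2ra, Ikzf2, Ctla4 and Csf2 for the exTreg contrasts. The rule also took up to 4 members of each described list with the smallest p. Csf2 did not pass the count filter and was not tested.

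Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names. Counts of genes that overlap another annotated gene are uncertain without strand, which among the named genes with coordinates holds for B3gnt2, Bcl2, Bcl2a1d, Bcl6, Ccr9, Cd160, Cd27, Cd274, Cxcr6, Cyp4f18, Cysltr1, Dlg2, Ebf1, Elf1, Foxp3, Galnt14, Gata3, Gbp4, Gimap7, Hk1, Igtp, Ikzf2, Ikzf4, Il2, Il21, Il2rg, Il4ra, Il5, Maf, Pim1, Rorc, Sema6d, St6gal1, Stat3, Stat4, Stat5a, Tmem176b, Tnfrsf18, Ufsp2 and Xist. Il22 and Iltifb are near-identical copies, and Bcl2a1d and Klrc1 have close paralogs, so their reads may be split between copies.

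The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0 (Wald test), the batch number as a block, library set and reporter as a fixed term, each library set alone, the YFP-sorted batches alone, each genotype alone, only the 2 groups compared, an estimated correlation for the lists, a threshold of 0.01 for shared calls, and each library left out in turn. Some sets of libraries were also set aside after the data had been seen.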

Results

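The series asked how Tregs that lose Foxp3 and gain IL-17 differ from stable Tregs, and whether 1 altered copy of Ptpn2 (floxed in vivo, Ptpn2+/- in culture), which encodes a tyrosine phosphatase of JAK and STAT proteins, changes either population. Gene counts were available for 32 libraries. The in vivo groups were Tregs (4 WT, 6 Het) and exTregs (4 WT, 6 Het), and the cultured groups were Tregs kept in IL-6 (3 WT, 3 Het) and the exTregs that arose beside them (3 WT, 3 Het). Depth ran from 5214378 to 12364409 counts in in vivo Tregs and from 5710971 to 10799970 in in vivo exTregs. It ran from 6580564 to 11025214 counts in cultured Tregs and from 7220493 to 11018131 in cultured exTregs. In vivo exTreg libraries detected fewer genes (11098 ± 303 in 6 Het and 11029 ± 584 in 4 WT libraries) than in vivo Treg libraries (12441 ± 367 in 6 Het and 12426 ± 420 in 4 WT).

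Ptpn2 (chromosome 18, 67665511 to 67724595, minus strand) was measured first because its genotype defines the groups. Cultured Het Tregs held 69.2 ± 6.503 CPM (n = 3) and cultured WT Tregs 101 ± 13.3 CPM (n = 3), a log2 difference of -0.55 with a 95% interval of -0.96 to -0.14. Cultured Het exTregs held 58.6 ± 8.72 CPM (n = 3) and WT exTregs 78.6 ± 12.0 CPM (n = 3), a log2 difference of -0.42 with an interval of -0.83 to -0.02. In vivo Het Tregs held 177 ± 24.8 CPM (n = 6) against 214 ± 34.7 CPM in WT (n = 4), a log2 difference of -0.27 with an interval of -0.57 to 0.02. In vivo Het exTregs held 190.2 ± 36.0 CPM (n = 6) against 190.02 ± 15.5 CPM in WT (n = 4), with an interval of -0.30 to 0.30 around a log2 difference of 0.00. None of these passed after Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test (adjusted p = 0.68 and 1 in cultured Tregs and exTregs, and 1 in both in vivo cell types). For this gene alone the unadjusted p was 0.012 in cultured Tregs and 0.043 in cultured exTregs, and the Het library was the lower one in 3 of 3 same-batch pairs of each. Counts cover the whole gene, so reads of a transcript that lacks a floxed part would still count. The part deleted is not given in the sources used here.

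Foxp3 (chromosome X, 7573644 to 7595245), the lineage factor of Tregs, and Il17a (chromosome 1, 20730905 to 20734496), a defining Th17 cytokine, were used in the sort, so their levels check the gates and are no finding. Foxp3 stood at 54.0 ± 9.60 CPM in in vivo Tregs and 2.20 ± 2.85 CPM in exTregs (n = 10 each), and at 122 ± 43.7 and 6.89 ± 2.83 CPM in culture (n = 6 each). Il17a stood at 1.41 ± 0.590 CPM in in vivo Tregs and 11552 ± 4095 CPM in exTregs, and at 13.3 ± 18.7 and 633 ± 201 CPM in culture. The 2 cultured Treg libraries of batch 7617 held most Il17a among the cultured Tregs, 25.9 CPM in WT and 46.0 CPM in Het.

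**Figure D1:**
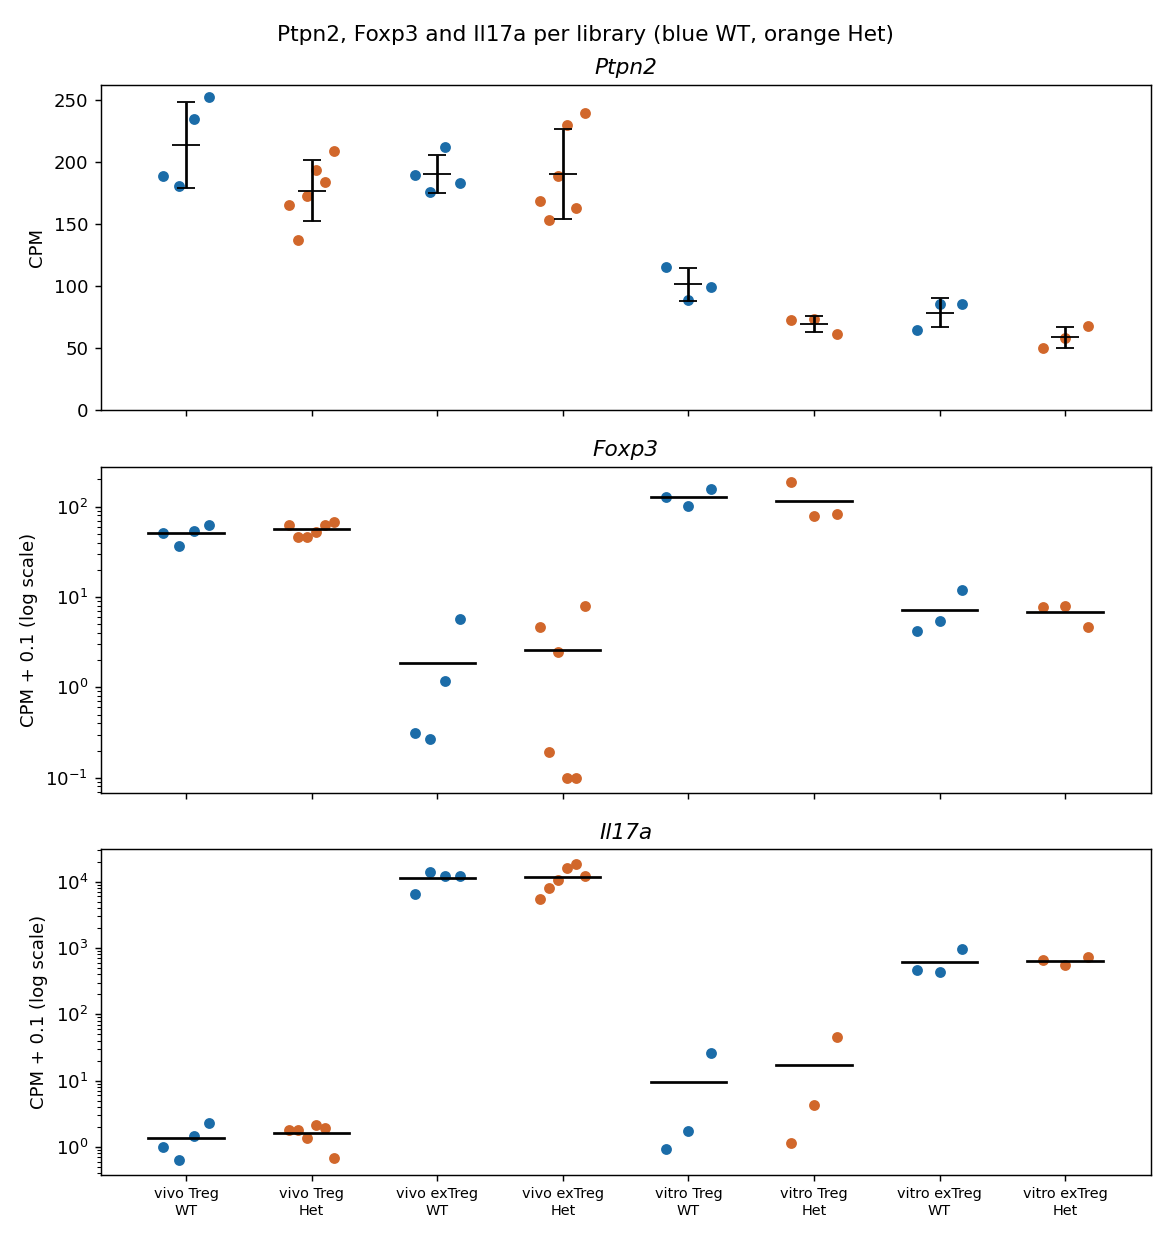
Ptpn2 (linear axis, with mean and SD) and Foxp3 and Il17a (log axis of CPM + 0.1, with the mean as a line) in each library, as points, for the 8 groups of 3 to 6 libraries. Cultured WT Tregs lie between 89.05 and 115.4 CPM of Ptpn2 and cultured Het Tregs between 61.7 and 73.6 CPM. Cultured exTregs overlap, at 64.75 to 85.75 CPM in WT and 50.08 to 67.5 CPM in Het, and so do the in vivo groups.

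In vivo, most tested genes of the Th17 program were higher in exTregs than in Tregs. Besides the sorted cytokine, Il17f rose from 22.6 ± 9.26 to 15824 ± 3228 CPM (log2 9.42, SE 0.25), Il22, a cytokine that acts on epithelium, by a log2 of 10.40 (SE 0.39), and Ccl20, the ligand of Ccr6, from 3.19 ± 1.65 to 918 ± 257 CPM (n = 10 each). Il21, a cytokine that sustains Th17 cells, rose from 4.23 ± 2.27 to 235 ± 71.5 CPM, and the IL-23 receptor gene Il23r from 3.41 ± 1.71 to 178 ± 67.5 CPM. Rorc, which encodes RORgt, the lineage factor of Th17 cells, rose by a log2 of 3.61 (SE 0.16), and the chemokine receptor Ccr6 by 2.48 (SE 0.20). Each rose in 10 of 10 same-batch pairs. Of the 19 tested genes of the Th17 list 16 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 1.8e-56, and adjusted p = 6.1e-06 with an estimated correlation). Il17a stands in that list and was used in the sort. Il22 shares reads with its near-identical copy Iltifb (7672 reads in exTregs and 6 in Tregs), so the level of each is uncertain.

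Genes of Treg identity fell. Lrrc32, which encodes GARP, the surface anchor of latent TGF-beta, fell from 286 ± 54.5 to 1.22 ± 2.04 CPM (log2 -8.30, SE 0.44). Ikzf2 and Ikzf4, which encode the transcription factors Helios and Eos, fell by a log2 of -3.91 (SE 0.22) and -4.63 (SE 0.33). Gpr83 fell by -6.16 (SE 0.54), Klrg1, a receptor of terminally differentiated cells, by -5.59 (SE 0.60), Folr4, the folate receptor family member of Tregs, by -4.37 (SE 0.38), and the cytotoxic protease Gzmb by -4.21 (SE 0.27). Smaller falls were those of Tnfrsf18, the costimulatory receptor GITR, at -2.16 (SE 0.13), Ctla4, an inhibitory receptor, at -1.12 (SE 0.22), and Il2ra, the IL-2 receptor alpha chain, at -0.79 (SE 0.09), from 3443 ± 337 to 2003 ± 305 CPM. Of 25 tested genes of the Treg list 19 fell and 4 rose, and 20 fell and 4 rose when adjusted over the list alone (camera adjusted p = 3.9e-14, and adjusted p = 0.0037 with an estimated correlation). The genes that rose were Il2rb, Capg, Nt5e and Il10, named after their values were seen. Foxp3 is in the list and was used in the sort. The rule also named Slc14a1, a urea transporter, with 30 reads in exTregs and 2531 in Tregs, and Tnfrsf8, the receptor CD30, which fell by -4.43 (SE 0.37).

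T cell activation genes were higher in exTregs. Both populations had been stimulated alike before the sort, but the exTreg gate kept only cells that secreted IL-17 after it. A stronger response to stimulation and the cell type therefore cannot be told apart here. Il2, the T cell growth factor, rose from 15.1 ± 6.34 to 2312 ± 491 CPM (log2 7.22, SE 0.25), and Cd40lg, the CD40 ligand, from 24.2 ± 7.82 to 535 ± 170 CPM (log2 4.43, SE 0.22). The early growth response gene Egr2 rose by 1.88 (SE 0.15) and Dusp2, a phosphatase of MAP kinases, by 1.30 (SE 0.12). Of 20 tested genes of the immediate early and TCR activation list 14 rose and 2 fell, and 15 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.8e-13, and adjusted p = 0.029 with an estimated correlation). Outside the lists, the hematopoietic cytokine Il3 rose by a log2 of 8.12 (SE 0.60) and the inhibitory lectin receptor Klrc1 by 6.95 (SE 0.42).

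Cytokines of the Th1 and Th2 lineages rose beside those of the Th17 lineage, with wide spread between libraries. Ifng, the Th1 cytokine, rose from 2.35 ± 1.93 to 295 ± 330 CPM (log2 6.83, SE 0.61) and Stat4, which relays IL-12 signals, by 1.67 (SE 0.16), while Tbx21, the Th1 lineage factor T-bet, fell by -0.93 (SE 0.18). The chemokine receptor Cxcr3 rose by 2.08 (SE 0.17). Il5, Il13 and Il4, the Th2 cytokines, rose by 6.33 (SE 0.84), 5.29 (SE 0.71) and 4.95 (SE 0.70). Il5 reached 1396 ± 2671 CPM in exTregs (n = 10). Of 14 tested Th1 genes 8 rose and 3 fell (camera adjusted p = 0.040, and adjusted p = 0.39 with an estimated correlation), and of 9 tested Th2 genes 6 rose and 1 fell (camera adjusted p = 0.020, and adjusted p = 0.45 with an estimated correlation). Counts adjusted over the list alone were the same in both. With the batch number as a block the Th1 list no longer passed (camera adjusted p = 0.054).

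Most tested tissue homing genes also rose. Cxcr6, a receptor of tissue-resident T cells, rose from 236 ± 46.9 to 2362 ± 461 CPM, Ccr4, a skin and Th2 homing receptor, by a log2 of 1.52 (SE 0.14), and Lgals3, which encodes galectin-3, by 2.98 (SE 0.27). Of 17 tested genes of the tissue homing list 12 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 8.3e-10, adjusted p = 0.077 with an estimated correlation, and 0.0018 with an estimated correlation and the batch number as a block). Apoptosis genes of opposed function rose together. The pro-apoptotic Bcl2l11 rose by 1.31 (SE 0.15), the death receptor ligand Fasl by 2.52 (SE 0.29) and the pro-survival Bcl2a1d by 1.87 (SE 0.16). Of 14 tested apoptosis genes 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.040 with an estimated correlation, or 0.11 with the block added).

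Some interferon-stimulated genes fell in exTregs. The GTPases Iigp1, Igtp and Gbp3, which act against intracellular pathogens, fell by a log2 of -3.15 (SE 0.23), -1.41 (SE 0.14) and -1.41 (SE 0.11), and Gbp4 by -0.89 (SE 0.17). Of 26 tested genes 12 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 1.0e-04, and adjusted p = 0.45 with an estimated correlation). Signalling genes downstream of IL-6 were split. Il6st, the shared receptor chain gp130, fell by -1.95 (SE 0.24), Stat3 by -0.89 (SE 0.11) and its feedback inhibitor Socs3 by -1.34 (SE 0.21), while the kinase Jak2 rose by 1.42 (SE 0.21). Of the 12 tested genes of that list 4 rose and 5 fell, and of the 13 of the IL-2 and STAT5 list 4 rose and 7 fell, or 4 and 8 when adjusted over the list alone. Stat5a fell by -0.82 (SE 0.11) and Il2rb, the IL-2 receptor beta chain, rose by 0.40 (SE 0.07). Neither list passed camera (adjusted p = 0.74 and 0.30).

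Other lists moved in part. Genes of naive cells and lymphoid homing went both ways, with 5 of 15 higher and 6 lower: the lymph node homing receptor Sell fell by -2.68 (SE 0.27), the costimulatory receptor Cd27 by -3.85 (SE 0.27) and the quiescence factor Klf2 by -1.69 (SE 0.17), while Il7r, the IL-7 receptor, rose by 1.08 (SE 0.20). Inhibitory receptors also divided, with 4 of 10 higher and 4 lower: Cd160 rose by 4.20 (SE 0.28), Havcr2, which encodes TIM-3, by 2.18 (SE 0.14) and Cd274, which encodes PD-L1, by 0.85 (SE 0.15), while Lag3 fell by -2.29 (SE 0.33). Of 13 tested phosphatases 5 rose and 2 fell, among them the ERK phosphatase Dusp6 at 2.11 (SE 0.31) and Ptpn1, the closest relative of Ptpn2, at -0.73 (SE 0.13). Ptpn2 itself stood at 192 ± 33.3 CPM in Tregs and 190.2 ± 28.3 CPM in exTregs, a log2 difference of -0.03 (SE 0.10). Bcl6, the follicular helper factor, rose by 2.57 (SE 0.19) in a list with 5 of 10 higher and 3 lower (4 lower when adjusted over the list alone). Of 17 glycolysis genes 1 rose and 3 fell, led by hexokinase Hk1 at -1.36 (SE 0.16). For glycolysis the median log2 change was 0.14 and the mean -0.08, and for stress genes both were negative (-0.26 and -0.31) while camera pointed up. Of 27 cell cycle genes 0 rose and 1 fell, the replication helicase subunit Mcm2, named after its value was seen, and of 13 stress genes 4 rose and 2 fell. Apart from the follicular helper list, counts adjusted over the list alone were the same. None of these lists passed camera (adjusted p = 0.11 to 0.74).

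Markers of other cells were checked beside these groups. Of 8 CD4 lineage genes 4 rose (5 when adjusted over the list alone), including Cd4 at 0.69 (SE 0.16) and the TCR kinase Zap70 at 0.55 (SE 0.08), with camera adjusted p = 0.069 (0.035 with the batch block), and adjusted p = 0.461 with an estimated correlation (0.115 with the block). Of 3 tested gamma-delta and innate-like markers 2 rose (3 when adjusted over the list alone), 1 of them 5830411N06Rik at 4.36 (SE 0.41) and the other Il7r (camera adjusted p = 0.016, and adjusted p = 0.15 with an estimated correlation). Of 4 tested plasma cell markers 3 rose, among them the secretory factor Xbp1 at 0.91 (SE 0.07), and 1 more fell when adjusted over the list alone (camera adjusted p = 0.040, adjusted p = 0.17 with an estimated correlation and 0.054 with the block). Of 7 B cell markers 1 passed, Cd19, from 0.564 ± 0.477 to 5.09 ± 5.03 CPM. In the exTreg Het libraries of batches 20190 and 20191, Cd19 stood at 18.1 and 6.32 CPM, Fcer2a at 16.7 and 15.8 CPM and the MHC class II gene H2-Aa at 109.5 and 105.5 CPM. The other 8 in vivo exTreg libraries reached at most 7.14, 7.44 and 37.6 CPM. Of 7 myeloid markers 0 passed, of 4 CD8 and NK markers 1 rose, of 6 dendritic cell markers 2 rose and 1 fell, and of 1 erythroid gene 0 passed, with the same counts adjusted over the list alone. The passing genes, named after their values were seen, were Klrk1, higher, Xcr1 and H2-Aa, higher, and Bst2, lower. The CD8 and NK median was -0.55 with a mean of 0.88, and the dendritic cell median -0.11 with a mean of 0.18. Xist rose by 0.67 (SE 0.19), and the Y-linked genes did not pass the count filter.

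In this in vivo contrast 1840 genes rose and 1818 fell of 10624 tested. Within library set 1 alone 2176 genes passed and within set 3 alone 2284, and with WT libraries alone 1558. The sorts also differ in RNA: Malat1, a nuclear noncoding RNA, stood at 1533 ± 315 CPM in Het and 1405 ± 116 CPM in WT Tregs and at 3141 ± 1139 and 2845 ± 500 CPM in Het and WT exTregs (n = 6, 4, 6 and 4).

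**Figure D2:**
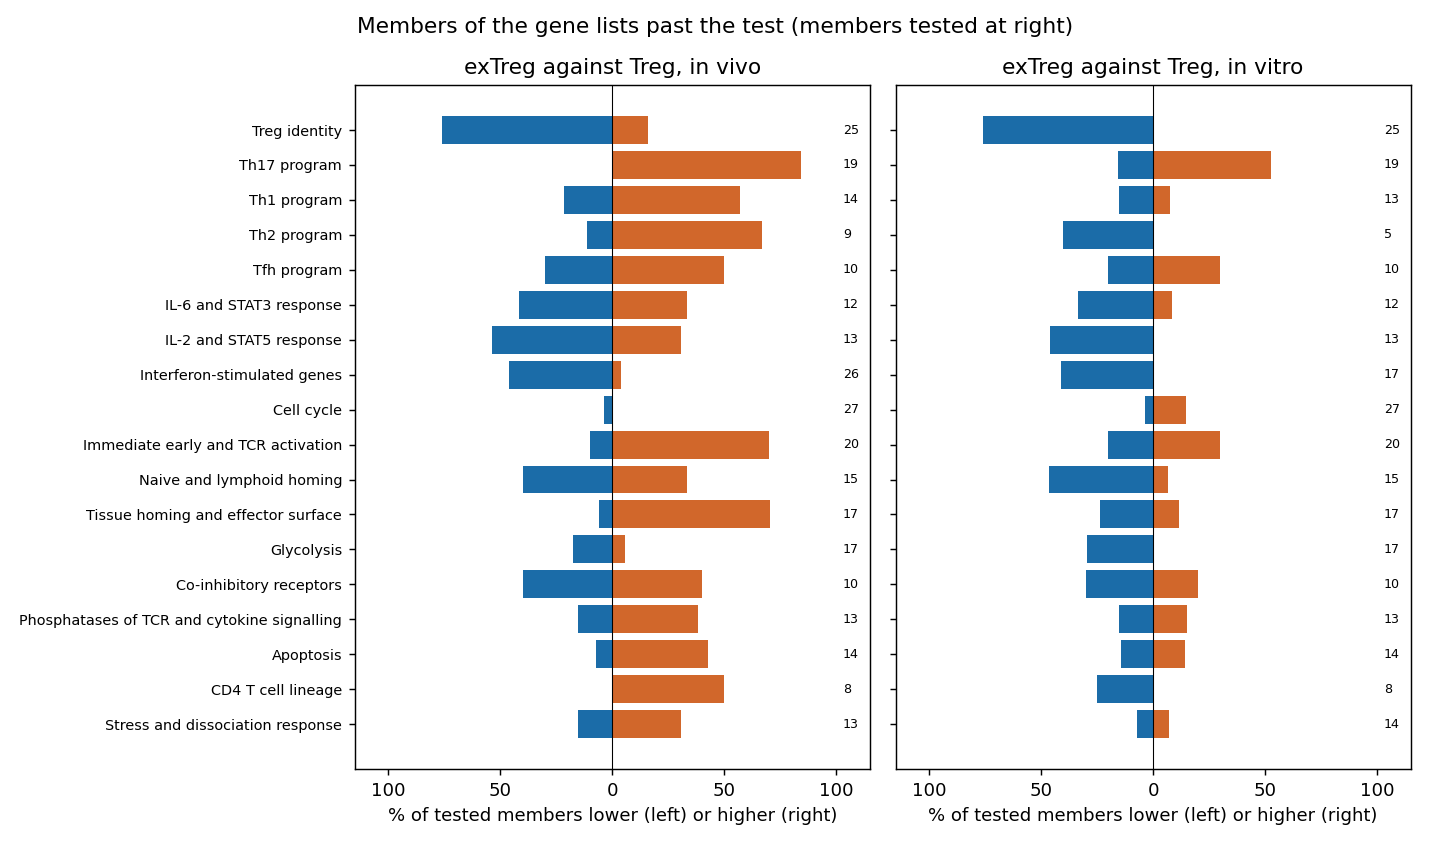
Share of tested members that were lower (left, blue) or higher (right, orange) in exTregs than in Tregs, in percent, for lists with at least 8 members tested in any comparison, in vivo (left panel) and in vitro (right panel). The Th17 list has 16 of 19 genes higher in vivo and 10 of 19 in vitro, and the Treg list 19 of 25 lower in each.

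In culture, exTregs also gained Th17 cytokines, with smaller changes. Il17f rose from 102 ± 127 to 3989 ± 936 CPM (log2 5.34, SE 0.73), Ccl20 from 3.72 ± 3.23 to 85.7 ± 19.3 CPM (log2 4.68, SE 0.46), Il21 from 18.7 ± 5.58 to 108 ± 20.1 CPM and Il23r from 4.88 ± 2.46 to 20.8 ± 6.00 CPM (n = 6 each). Il22 rose by a log2 of 3.63 (SE 0.89) but stayed at 2.69 ± 2.97 CPM. The ion transport gene Tmem176b rose by 3.60 (SE 0.37) and Cxcr6 by 0.85 (SE 0.15). Rorc stood at 46.9 ± 24.8 CPM in Tregs and 98.7 ± 34.0 CPM in exTregs, higher in 6 of 6 pairs. Its log2 difference of 1.10 (SE 0.36) missed the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.054) and passed with the batch number as a block (adjusted p = 5.8e-04 in the same test), with DESeq2, without the count filter or without the Het Treg library of batch 8317. Ccr6 stood at 95.6 ± 36.3 CPM in Tregs and 79.3 ± 34.0 CPM in exTregs and did not pass. Of the 19 tested Th17 genes 10 rose and 3 fell, and 11 rose and 4 fell when adjusted over the list alone (camera adjusted p = 7.6e-07, and adjusted p = 0.16 with an estimated correlation). The genes that fell were the transcription factors Batf and Maf and the leukotriene receptor Ltb4r1, named after their values were seen.

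Treg identity genes fell in culture too. Gpr83 fell from 111 ± 45.4 to 2.65 ± 3.35 CPM (log2 -5.40, SE 0.74), Lrrc32 by -4.77 (SE 0.65), the inhibitory receptor Tigit from 142 ± 21.4 to 5.99 ± 1.80 CPM (log2 -4.58, SE 0.22), Ctla4 by -3.34 (SE 0.21) and Ikzf2 by -3.17 (SE 0.35). Gzmb fell by -7.11 (SE 0.82), the cytokine signalling inhibitor Socs2 by -3.86 (SE 0.32) and Il2ra by -0.99 (SE 0.19). Of 25 tested genes 19 fell and 0 rose, and 21 fell when adjusted over the list alone (camera adjusted p = 6.8e-38, adjusted p = 0.029 with an estimated correlation, and 0.081 with the batch block added).

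Members of several other groups fell among cultured exTregs. The chemokine receptors Ccr2 and Ccr5, of the homing list, which as a list did not pass camera, fell by a log2 of -6.46 (SE 0.56) and -4.52 (SE 0.54), Sell by -4.29 (SE 0.46), Klf2 by -3.89 (SE 0.58), the chromatin organizer Satb1 by -1.65 (SE 0.22) and Cd27 by -1.51 (SE 0.27). Of 15 tested genes of the naive list 7 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 3.2e-05, and adjusted p = 0.080 with an estimated correlation). The interferon-stimulated genes that fell included Gbp4 at -4.12 (SE 0.33), Isg20, an exonuclease, at -2.95 (SE 0.31), Igtp at -2.84 (SE 0.22) and Gbp3 at -2.45 (SE 0.30). Of 17 tested 7 fell and 0 rose, and 9 fell when adjusted over the list alone (camera adjusted p = 1.0e-08, and adjusted p = 0.080 with an estimated correlation). Gata3, the Th2 lineage factor, fell from 186 ± 72.5 to 24.6 ± 5.52 CPM and Il4ra, the IL-4 receptor, by -0.67 (SE 0.16). Of 5 tested Th2 genes 2 fell, and 3 when adjusted over the list alone (camera adjusted p = 9.6e-04, and adjusted p = 0.060 with an estimated correlation). Tbx21 fell by -3.53 (SE 0.53) and Stat4 rose by 1.52 (SE 0.19). Of 13 tested Th1 genes 1 rose and 2 fell, or 1 and 3 when adjusted over the list alone (camera adjusted p = 0.96).

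Some cytokine signalling genes fell. Il2rg, the common gamma chain, fell by a log2 of -0.63 (SE 0.10) and the kinase Pim2 by -1.58 (SE 0.29). Of 13 tested genes of the IL-2 and STAT5 list 6 fell, and 8 when adjusted over the list alone (camera adjusted p = 1.5e-04, and adjusted p = 0.17 with an estimated correlation). Stat3 fell by -1.18 (SE 0.19), Socs3 by -3.00 (SE 0.52) and the kinase Pim1 by -0.91 (SE 0.15). Of 12 tested genes of the IL-6 and STAT3 list 4 fell and 1 rose, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation). Activation genes were mixed, with 6 of 20 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.26): Il2 rose by 2.59 (SE 0.23) and Cd40lg by 2.27 (SE 0.18), while the activation marker Cd69 fell by -2.06 (SE 0.26) and the AP-1 gene Fosl2 by -1.64 (SE 0.20). Of 17 glycolysis genes 5 fell, also when adjusted over the list alone, led by the glucose transporter Slc2a3 at -1.88 (SE 0.20) (camera adjusted p = 0.012, and adjusted p = 0.47 with an estimated correlation). Of 27 cell cycle genes 4 rose, among them Mcm3 at 0.90 (SE 0.17), and 1 fell, Mcm6 at -0.99 (SE 0.16), with the same counts adjusted over the list alone (camera adjusted p = 0.039, adjusted p = 0.68 with an estimated correlation, and 0.081 at the preset correlation with the block).

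Further named genes covered other functions. Dlg2, a synaptic scaffold gene, rose from 6.84 ± 1.47 to 128 ± 10.1 CPM (log2 4.23, SE 0.17), Amica1, which encodes the adhesion molecule JAML, by 3.98 (SE 0.40), Olfm2 by 4.01 (SE 0.49) and Cd160 by 3.33 (SE 0.29). Gimap7, a GTPase of lymphocytes, fell from 134 ± 31.1 to 5.39 ± 1.88 CPM (log2 -4.64, SE 0.25), Cyp4f18, a leukotriene hydroxylase, by -6.48 (SE 0.94) and Treml2 by -4.25 (SE 0.40). Of 10 inhibitory receptor genes 2 rose and 3 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.039, adjusted p = 0.35 with an estimated correlation, and 0.45 at the preset correlation with the block). Their median log2 change was 0.005 and the mean -0.35. Of 10 follicular helper genes 3 rose (4 when adjusted over the list alone), among them Cd200 at 1.03 (SE 0.15), and 2 fell, among them the costimulatory receptor Icos at -2.61 (SE 0.24). Of 17 homing genes 2 rose and 4 fell, with Lgals3 at -2.01 (SE 0.40). Of 13 phosphatases 2 rose and 2 fell, or 4 and 3 when adjusted over the list alone, with Ptpn1 at -0.96 (SE 0.10), and Ptpn2 stood at 85.2 ± 19.8 CPM in Tregs and 68.6 ± 14.4 CPM in exTregs, a log2 difference of -0.30 (SE 0.13) that did not pass. Of 14 apoptosis genes 2 rose and 2 fell, with Bcl2l11 at -1.43 (SE 0.20). The median and mean were -0.12 and 0.005 for phosphatases and -0.06 and 0.02 for apoptosis genes. Homing and apoptosis counts were the same adjusted over the list alone. These 4 lists, of follicular helper, homing, phosphatase and apoptosis genes, did not pass camera (adjusted p = 0.25 to 0.98).

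Markers of other cells were also checked in culture. Of 3 tested plasma cell markers 1 fell, Prdm1, which also encodes the T cell repressor Blimp-1, with 4 reads in exTregs and 194 in Tregs. Of 5 dendritic cell markers 1 fell (H2-Ab1, named after its value was seen), or 2 when adjusted over the list alone. Of 1 B cell, 2 myeloid and 1 CD8 and NK marker 0 passed, while adjusted over the list alone the B cell marker fell and 1 myeloid marker rose and 1 fell. Of 2 gamma-delta markers 1 rose and 1 fell. Of 8 CD4 lineage genes 2 fell, Cd5 and Cd28, named after their values were seen, and 1 more rose when adjusted over the list alone. Of 14 stress genes 1 rose and 1 fell, or 2 and 1 when adjusted over the list alone, and Xist did not pass. No erythroid gene was tested.

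In this contrast 638 genes rose and 951 fell of 10760 tested. The count was 1024 without the WT Treg library of batch 8317, 1038 without the Het exTreg library of batch 7617 and 1006 without the Het Treg libraries of batches 81017 and 7617, a pair set aside after the data were seen because Malat1 and 45S ribosomal RNA were low in them. It was 442 with WT and 471 with Het libraries alone.

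The exTreg changes were compared between the experiments. Of 10147 genes tested in both, 284 rose in both and 417 fell in both, where 98.4 and 159.5 would be shared by independent lists. A further 114 rose in vivo and fell in vitro (158.8 for independent lists), and 28 fell in vivo and rose in vitro (98.8). No library was shared. Across these genes, which are not independent replicates, Pearson's r of the log2 changes was 0.42 and Spearman's rho 0.25.

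The test of the difference itself found the exTreg change more positive in vivo for most tested Th17 and activation genes. A more positive change is not always a larger one, since Cd69, Fosl2, Ccr2 and Lgals3 fell in culture. Il2 differed by a log2 of 4.63 (SE 0.33), Il21 by 3.28 (SE 0.35), Ccr6 by 2.78 (SE 0.35), Cxcr6 by 2.44 (SE 0.21) and the IL-1 receptor gene Il1r1 by 5.38 (SE 0.45). Il17a differed by 7.35 (SE 0.81), but it was used in the sort, so its difference may reflect the gates and is no finding. It also stands in the Th17 list. Of 19 Th17 genes 14 were higher in this contrast and 0 lower, or 18 and 0 when adjusted over the list alone (camera adjusted p = 1.1e-24, and adjusted p = 0.0013 with an estimated correlation). Cd40lg differed by 2.16 (SE 0.29), Cd69 by 2.16 (SE 0.27) and Fosl2 by 2.35 (SE 0.29), and of 20 activation genes 11 were higher and 1 lower, or 14 and 1 when adjusted over the list alone (camera adjusted p = 1.1e-11, and adjusted p = 0.017 with an estimated correlation). Ccr2 differed by 6.62 (SE 0.55) and Lgals3 by 4.99 (SE 0.48), and of 17 homing genes 10 were higher and 1 lower, or 11 and 1 when adjusted over the list alone (camera adjusted p = 2.6e-13, and adjusted p = 0.017 with an estimated correlation). Foxp3 (log2 -0.56, SE 0.73) and Ptpn2 (0.26, SE 0.16) did not pass.

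**Figure D3:**
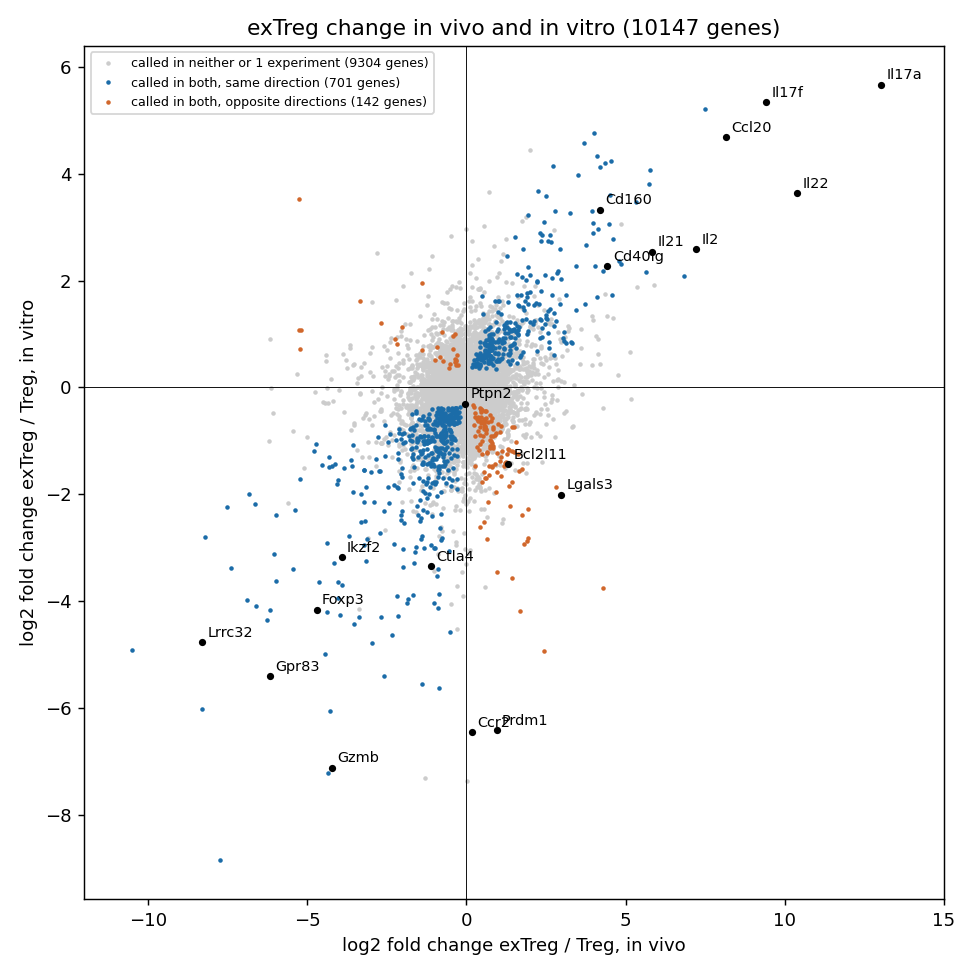
Fitted log2 fold change of exTregs over Tregs in vivo (horizontal axis) and in vitro (vertical axis) for the 10147 genes tested in both, 1 point per gene, with blue points called in both in the same direction, orange points called in both in opposite directions and black points for labelled genes. Il17a, Il17f, Ccl20 and Il2 lie at the upper right, and Lrrc32, Gpr83, Foxp3 and Gzmb at the lower left.

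Some genes moved in opposite directions or in 1 experiment. Tigit differed by a log2 of 4.06 (SE 0.24), Ctla4 by 2.22 (SE 0.34) and Socs2 by 2.98 (SE 0.38), since they fell further in culture, and of 25 Treg genes 9 were higher and 1 lower, or 10 and 3 when adjusted over the list alone (camera adjusted p = 1.6e-04, and adjusted p = 0.14 with an estimated correlation). Il10, an anti-inflammatory cytokine, held 4693 reads in in vivo exTregs and 1693 in Tregs, against 33 and 112 in culture. Prdm1 held 3444 and 2095 reads in vivo and 4 and 194 in culture, and with Xbp1 at 0.90 (SE 0.12) it was among 3 of 4 plasma cell markers that were higher (camera adjusted p = 1.6e-04, and adjusted p = 0.017 with an estimated correlation). Bcl2l11 differed by 2.74 (SE 0.26), and of 14 apoptosis genes 3 were higher and 0 lower (camera adjusted p = 0.011, adjusted p = 0.026 with an estimated correlation, and 0.068 with the block added). Icos differed by 3.04 (SE 0.28), Cd200 by -1.80 (SE 0.23), Gata3 by 2.55 (SE 0.39) and Ccr4 by 1.86 (SE 0.34). Of 8 CD4 lineage genes 4 were higher, among them the costimulatory receptor Cd28 at 1.74 (SE 0.21) (camera adjusted p = 0.0016, adjusted p = 0.18 with an estimated correlation, and 0.018 with the block added). Of 10 inhibitory receptor genes 4 were higher and 2 lower (camera adjusted p = 0.0013, adjusted p = 0.053 with an estimated correlation, and 0.032 with the block added).

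Among the largest differences, several rested on few reads in 1 arm. Ccr9, a gut homing receptor, held 1163 reads in in vivo exTregs and 57 in Tregs, against 24 and 181 in culture. Cysltr1, a leukotriene receptor, held 3871 and 791 in vivo and 3 and 110 in culture, where the pooled ratio was 0.0245 with an exact binomial 95% interval of 0.00499 to 0.0736 for counting error only. Cyp4f18 held 33 and 7 reads in vivo and 20 and 1560 in culture. Nod1, an intracellular sensor of bacterial cell walls, held 0 reads in in vivo exTregs and 2015 in Tregs, at least 645-fold lower against a floor of 3 reads over the group, and 19 and 464 in culture. The integrin chain gene Itga5 held 40 and 521 reads in vivo and 1591 and 662 in culture, and Scamp1, Atp6v0d2 and Galnt14 held 34, 9 and 7 reads in in vivo exTregs and 364, 349 and 290 in Tregs, against 1266, 2309 and 553 in cultured exTregs and 669, 2812 and 393 in cultured Tregs. The difference of Cyp4f18 was not called without the WT in vivo exTreg library of batch 23743, nor that of Nod1 without the WT cultured exTreg library of batch 7617. In all, 1154 genes had a higher and 779 a lower change in vivo, of 11496 tested. Reporter and library set differ between the experiments too, and the labels conflict on the in vitro strain. The compared cells differ as well. Cultured exTregs came from cultures of sorted Tregs, while past reporter expression of in vivo exTregs was not tested. Cultured Tregs were kept for 72 h with IL-6 and beads, and in vivo Tregs were not. This difference is therefore not that of the setting alone.

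The remaining lists of the difference were smaller. Of 14 Th1 genes 2 were higher, of 9 Th2 genes 3 (4 when adjusted over the list alone), of 12 genes of the IL-6 and STAT3 list 3 with 1 lower, of 13 of the IL-2 and STAT5 list 4 (and 2 lower when adjusted over the list alone), of 26 interferon-stimulated genes 6 with 1 lower, of 15 naive genes 8 with 3 lower (9 and 3 when adjusted over the list alone), and of 3 gamma-delta markers 2. These 7 lists passed camera (adjusted p = 0.0088 to 0.034) and did not with an estimated correlation (adjusted p = 0.14 to 0.62). Of 10 follicular helper genes 2 were higher and 2 lower, of 27 cell cycle genes 1 and 2 (1 and 1 when adjusted over the list alone), of 17 glycolysis genes 1 and 0, of 13 phosphatases 4 and 0, of 14 stress genes 1 and 2, and of 6 dendritic cell markers 2 and 1 (3 and 1 when adjusted over the list alone). The follicular helper list had a median of -0.25 and a mean of 0.11, and CD8 and NK markers a median of 3.27 while camera pointed down. Of 7 B cell, 7 myeloid, 5 CD8 and NK, 1 erythroid and 1 Xist marker 0 passed. None of these lists passed camera.

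The genotype comparison in in vivo Tregs asked whether stable Tregs of mice with 1 floxed Ptpn2 allele differ from those of WT mice. The labels name no Cre recombinase, and no test here showed the allele to be deleted in either in vivo cell type, so calls or their absence in vivo do not show what the loss of a copy does. No gene passed in edgeR's quasi-likelihood test (0 of 10624, with 91 at an unadjusted p under 0.05 where chance gives 531), nor with DESeq2 (0, with 126). Among genes with an average log2 CPM of at least 2, those with the smallest p, none past the test, were the semaphorin Sema6d at 0.638 ± 0.485 CPM in Het (n = 6) and 3.31 ± 1.60 CPM in WT (n = 4), the glycosyltransferase B3gnt2 at 278 ± 37.4 and 354 ± 32.5 CPM, and Dusp2 at 142 ± 37.2 and 195 ± 34.3 CPM. Foxp3 stood at 55.9 ± 9.13 and 51.1 ± 10.9 CPM in Het and WT, and Il17a at 1.52 ± 0.528 and 1.25 ± 0.724 CPM. Camera at its preset correlation placed the activation list lower in Het (adjusted p = 8.6e-12, median log2 change -0.42), but this was lost with an estimated correlation (adjusted p = 0.17). The same held for the lists of Th17 genes (adjusted p = 8.7e-06, 0.19 with an estimated correlation), phosphatases (2.6e-05, 0.19), the cell cycle (0.0021, 0.41), inhibitory receptors (0.0021, 0.19) and IL-6 and STAT3 genes (0.012, 0.28), all lower, and for myeloid markers, higher (0.028, 0.28). No member of any list passed, over all genes or adjusted over the list alone. Among these members Ccl20 stood at 2.39 ± 1.17 CPM in Het and 4.39 ± 1.64 CPM in WT.

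In in vivo exTregs the same question was asked of the reporter-negative cells that secreted IL-17. Again 0 of 10624 genes passed in edgeR's quasi-likelihood test, with 1037 at an unadjusted p under 0.05 where chance gives 531. With exTregs fitted alone, 309 genes lay under 0.05 in that test, where chance gives 496. DESeq2 called 160 (89 higher and 71 lower in Het) in a fit of all in vivo libraries, which also shares 1 spread per gene. Among genes with an average log2 CPM of at least 2, the smallest Benjamini-Hochberg adjusted p of the quasi-likelihood test was 0.093, for Ufsp2, a protease of the UFM1 pathway, at 21.7 ± 5.85 CPM in Het (n = 6) and 52.5 ± 15.7 CPM in WT (n = 4). Cep152, a centriole gene, stood at 3.30 ± 2.47 and 16.3 ± 3.30 CPM and Spice1, a spindle gene, at 8.07 ± 2.66 and 0.522 ± 0.975 CPM, and all 3 were among the DESeq2 calls. Il17a stood at 11798 ± 4867 and 11183 ± 3242 CPM in Het and WT and Foxp3 at 2.50 ± 3.23 and 1.75 ± 2.57 CPM. No list passed camera, and 1 member was higher and 3 lower when adjusted over the list alone, namely Cd74, an MHC class II chaperone, higher, and Lrrc32, Bcl2 and Mcm5 lower. Cd74 reached 317 and 445 CPM in the Het exTreg libraries of batches 20190 and 20191 and at most 203 CPM in the other 8. Without these 2 libraries, set aside after the data were seen, 46 genes passed (15 higher and 31 lower). Leaving out 1 exTreg library gave 11 genes without Het 20190, 3 without Het 20191, 11 without Het 20193, 2 without Het 23935, 1 without WT 20192, 7 without WT 20085 and 18 without WT 23743. Library set 1 alone gave 9 genes and set 3 alone 0. All these fits shared 1 spread with the Tregs. With all in vivo libraries, 80 regroupings of the batches under exchanged genotype labels also gave exTreg calls. The highest gave 100 genes, and the median over all regroupings was 3.

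In cultured Tregs, 0 of 10760 genes passed between Het and WT in edgeR's quasi-likelihood test, with 732 at an unadjusted p under 0.05, and 0 passed with DESeq2 (939). The smallest p belonged to Elf1, an ETS transcription factor, at 64.6 ± 10.4 CPM in Het and 114 ± 13.6 CPM in WT (n = 3 each), the zinc finger gene Zfp81 at 1.76 ± 1.10 and 6.85 ± 0.972 CPM and Sestd1 at 4.35 ± 0.991 and 14.7 ± 4.00 CPM. None of them passed. Foxp3 stood at 116 ± 61.8 and 129 ± 28.6 CPM and Il17a at 17.1 ± 25.1 and 9.44 ± 14.2 CPM. No list passed camera and 0 members passed adjusted over the list alone. The Het library of batch 8317 decided this count: without it 439 genes passed (194 higher and 245 lower in Het, with Elf1, Zfp81 and Sestd1 among them), and 11 of the 12 libraries could be left out with 0 genes passing. The 2 other Het libraries held 677 and 763 CPM of Malat1, where the WT libraries held 1034 to 1356 CPM and the Het library of batch 8317 held 923 CPM.

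In cultured exTregs 0 of 10760 genes passed between Het and WT, with 220 at an unadjusted p under 0.05 in edgeR's quasi-likelihood test and 344 with DESeq2, which also called 0. The genes with the smallest p, none past the test, were Narf at 10.6 ± 1.63 CPM in Het and 23.5 ± 5.18 CPM in WT (n = 3 each), Marveld1 at 3.86 ± 1.37 and 10.2 ± 2.05 CPM, and the laminin chain Lama5 with 0 and 23 reads. Il17a stood at 647 ± 90.5 and 619.6 ± 303 CPM and Foxp3 at 6.70 ± 1.88 and 7.08 ± 4.05 CPM. Camera placed the activation list higher in Het (adjusted p = 0.0019, and adjusted p = 0.31 with an estimated correlation). Nfkbid, a nuclear regulator of NF-kB, stood at 862 ± 155 and 517 ± 82.3 CPM and the nuclear receptor Nr4a1 at 112 ± 18.4 and 68.7 ± 9.00 CPM. In all lists together Nfkbid was higher and the B cell factor Ebf1 lower when adjusted over the list alone, and 0 members passed over all genes.

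The interaction asked whether the genotype difference depended on the cell type. In vivo 0 of 10624 genes passed in edgeR's quasi-likelihood test (517 at an unadjusted p under 0.05), while DESeq2 called 11 (7 higher and 4 lower). Of the 3 genes with the smallest p among those with an average log2 CPM of at least 2, Fam174b held 0 reads in Het exTregs, 76 in WT exTregs, 433 in Het Tregs and 134 in WT Tregs, and the sialyltransferase St6gal1 had a log2 interaction of 1.51 (SE 0.36) and Ufsp2 of -1.37 (SE 0.33). Ptpn2 had 0.28 (SE 0.20), Foxp3 0.36 (SE 1.15) and Il17a -0.14 (SE 0.57). No list passed camera without the block. With the batch number as a block the Th17, activation and phosphatase lists were higher at the preset correlation (adjusted p = 0.0062, 0.0058 and 0.035) and not with an estimated correlation (adjusted p = 0.43, 0.67 and 0.43). Over all lists 1 member, Lrrc32, was lower when adjusted over the list alone. The count was 1 without the exTreg libraries Het 20190, WT 20085 or Het 23935, each in turn, and 6 without WT 23743.

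In culture 0 of 10760 genes passed for the interaction in edgeR's quasi-likelihood test (364 at an unadjusted p under 0.05) and 0 with DESeq2 (532). Among genes with an average log2 CPM of at least 2, the smallest p belonged to the valine catabolism gene Hibch, with a log2 interaction of -2.89 (SE 0.71), to Lama5, with 0 and 23 reads in Het and WT exTregs and 364 and 458 in Tregs, and to the mitochondrial assembly gene Tmem126b at -1.54 (SE 0.44). Ptpn2 had 0.12 (SE 0.27), Foxp3 0.09 (SE 0.57) and Il17a -0.78 (SE 1.45). No list passed camera, and 0 members passed adjusted over the list alone. Without the Het Treg library of batch 8317, 38 genes passed.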

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

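The splits of the libraries were planned, and the bounds of the transcript length test were set before that test was run. The tests of a mislabelled sample, of the position of the Het libraries, of Ptpn2 levels and of the shared spread were chosen after their results had been seen.

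Single libraries stood far from their group in 6 of 72 checks of in vivo groups, where chance marks about 1 in 20 groups, or 3.6. The 45S ribosomal RNA gene Rn45s stood at 4053 CPM in the Het exTreg library of batch 20190, against 142 to 369 CPM in the other 5. Foxp3 stood at 5.55 CPM in the WT exTreg library of batch 23934, against 0.166 to 1.08 CPM. Il21 stood at 9.20 CPM in the Het Treg library of batch 20086, against 1.75 to 3.56 CPM, and Rorc at 24.8 CPM in the Het Treg library of batch 20190, against 11.9 to 16.7 CPM. Il23r stood at 260.0 CPM in the WT exTreg library of batch 23743, against 123 to 129 CPM. Il2ra stood at 1390 CPM in the Het exTreg library of batch 20190, against 2097 to 2396 CPM.

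The exTreg change differed between in vivo and cultured cells, by a test of the difference itself, for 1933 genes. Of 40 splits, made by exchanging the experiment labels, 1 gave as many genes, the real one, and the highest other gave 1. The other splits mix in vivo and cultured libraries within groups. That widens the spread and lowers the count whether or not the exTreg change differs, so these splits cannot exclude chance. The largest fitted log2 differences were 8.22 for Cyp4f18, 8.00 for Ccr9, 7.35 for Cysltr1, 7.35 for Il17a and 7.26 for Prdm1, and -6.40 for Itga5, -6.04 for Scamp1, -5.75 for Nod1, -5.73 for Atp6v0d2 and -5.52 for Galnt14. Those of Prdm1, Itga5, Scamp1, Nod1 and Atp6v0d2 involve a group with 0 reads, depend on the prior count and are no bound. That of Il17a is no finding, because Il17a was used in the sort.

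The exTreg contrasts were set against other splits of the same libraries. In vivo, 1 of 100 splits gave as many genes as the real one (3658), and the highest other (1901) had the labels exchanged in 1 of the 10 same-batch pairs. Of the other splits 40 parted all pairs as the real one does. In culture, 1 of 100 splits gave as many as the real one (1589) and the highest other gave 1090, while the 31 other splits that parted all pairs gave 0. The other splits mix Tregs and exTregs, sorted apart by reporter and IL-17, within groups, which widens the spread and lowers their counts. They show that the cell labels separate the libraries, which the sort ensures, and not how many calls are due to chance. For the genotype in vivo the real count was 0 in Tregs, in exTregs and for the interaction. Every split gives at least 0, so that 100 of 100 gave as many says nothing about chance there (highest other 37, 100 and 3). Calls did arise under other splits, in 7 of them for Tregs, 80 for exTregs and 23 for the interaction. The median over the other splits was 3 genes for exTregs. Small counts of exTreg calls can therefore arise when batches are regrouped without regard to genotype. In culture the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real and the highest other count were both 0 for Tregs, exTregs and the interaction, and with a real count of 0 all 10 of 10 splits give as many whatever the data.

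The first pattern is the 439 genes that separated cultured WT Tregs from the Het Tregs of batches 81017 and 7617 once the Het library of batch 8317 was left out. That library held 72.3 CPM of Ptpn2, below the 89.05 to 115.4 CPM of the WT Treg libraries. This does not exclude a mislabelled library. Ptpn2 did not pass between the genotypes, and the WT cultured exTreg library of the same batch held 64.75 CPM. A bias by gene length stays open and is a candidate explanation: the higher genes had a median transcript length of 1766 and the lower genes of 3474 bases, a log2 difference of -0.98 (permutation p = 1e-05, the smallest these permutations can give, 388 genes with a length), while GC content differed by -0.66 percentage points (permutation p = 0.40). The permutations exchange genes, which are not independent replicates, so these p-values do not measure the spread between libraries. Across all genes single WT libraries showed rank correlations of change with length of -0.17 to 0.19 against the other WT libraries, and this contrast -0.16. The other Het libraries were placed on an axis from the WT Tregs (0) to these 2 libraries (1). The Het library of batch 8317 lay at -0.04. That position cannot speak for or against a genotype effect, because the genes were called only once this library was left out. The Het exTregs lay at -0.12 to 0.01, within the -0.11 to 0.15 of the WT libraries or just below. An effect of genotype common to all Het cells would shift them from the WT range toward 1. They could fall short of 1, because the genes were chosen on the libraries that set the scale. No such shift was seen in exTregs for these genes. An effect confined to Tregs is not excluded by these values, because no Het Treg library outside the choice of genes was left to place.

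The second pattern is the level of Ptpn2 in Het cells. Counts from 1 allele alone would give a log2 change of -1, and the lowest bounds of the 95% intervals were -0.57 in vivo and -0.96 in culture, both above it, the latter narrowly. A partly counted altered transcript, a higher output of the other allele, or a floxed allele left intact in vivo was not tested. In vivo the exTreg difference exceeded that of the Tregs by 0.28 (interval -0.15 to 0.70). By this interval, whether exTregs hold more cells with both alleles cannot be told apart from no difference. It comes from the fit without the batch block, so the pairing of Treg and exTreg libraries was not used.

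The last pattern is the unequal number of small p-values for genotype in vivo, 91 in Tregs and 1037 in exTregs. The groups differ in spread, with a biological coefficient of variation of 0.24 and 0.18 in Het and WT Tregs and 0.57 and 0.55 in exTregs, and the fit shares 1 spread. Fitting each cell type alone gave 309 genes in exTregs, where chance gives 496, and 536 in Tregs, where chance gives 505, so the shared spread is a candidate explanation. No biological explanation was tested for the counts themselves.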

How the results depend on the processing

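The alternatives were planned, except those that set more than 1 named library aside, which were chosen after seeing the data. RLE size factors kept all 9 gene counts within 1.5 times, and no scaling moved the median log2 change by more than 0.1. For in vivo exTregs against Tregs the count of 3658 became 2176 with library set 1 alone, 2284 with set 3 alone and 1558 with WT alone, from fewer libraries. It was 3863 without the filter, 4106 with DESeq2, 3991 with the replicate block, 3995 without the Het exTregs of batches 20190 and 20191, and 3244 to 3878 with 1 library left out. In culture 1589 became 442 with WT and 471 with Het alone and 1006 without the Het Tregs of batches 81017 and 7617, from fewer libraries. It was 2233 with DESeq2, 1740 with the block and 1024 to 2374 with 1 library left out. The count for the difference between experiments (1933) was 1722 without the filter, 2176 with the block, 2292 with DESeq2, 2438 without the Het exTregs of batches 20190 and 20191, and 1485 to 2284 with 1 library left out.

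The 0 genes for genotype in in vivo exTregs became 160 with DESeq2, 9 with library set 1 alone, 46 without the Het exTregs of batches 20190 and 20191, 1 without the exTregs of batches 20085 and 23745, and 0 to 18 with 1 library left out. These fits shared 1 spread per gene with the Tregs, whose own spread was smaller. The exTregs of batches 20085 (WT) and 23745 (Het) stood apart on principal components of the in vivo log2 CPM. WT 20085 lay at 108.1 on component 2, where the other in vivo libraries lay at -31 to 14.8. Het 23745 lay at -83.9 on component 3, where the others lay at -17.1 to 45.4. The in vivo interaction became 11 with DESeq2, 1 with either pair set aside and 0 to 6 with 1 library left out. Cultured Tregs gave 0 to 439 and the cultured interaction 0 to 38 with 1 library left out, and in vivo Tregs and cultured exTregs gave 0 to 0. The cause was not tested, beyond the tests given for the cultured Tregs. No paired analysis was possible for the in vivo genotype contrasts because each batch number holds 1 genotype. Elsewhere, among gene lists and named genes, the block ended or made only the list calls and the Rorc call printed beside those results. It also changed the counts of called genes for the exTreg contrasts and their difference, as given above. Lists past camera fell, with an estimated correlation, from 10 to 4 in vivo and from 10 to 1 in culture for exTregs, from 7 to 0 for in vivo Treg genotype, from 1 to 0 for cultured exTreg genotype and from 15 to 5 for the difference. Shared calls fell from 701 to 348 at an adjusted p under 0.01.

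Of 155 called gene results, 133 stayed called in every setting run. Of their 4438 values 23 lost the call, 16 of them with 1 genotype alone, and none changed direction. Of 1175 values of the 50 uncalled results 25 passed. Among uncalled values 46 changed sign. In the genotype contrasts of 3 against 3 libraries, counts were simulated with 1 spread shared by the groups. A log2 change of 1 was recovered for 27% (Tregs) and 30% (exTregs) of the changed genes. At that spread, most changes of that size or less would go undetected at this number.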

Other observations

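Single genes within the cultured Het Tregs were looked at only after the data had been seen, and the genes named here fall outside the rule for named genes. With the Het Treg library of batch 8317 left out, the genes higher in the other 2 Het libraries included Vmp1, an autophagy gene, at 2088 and 1571 CPM against 553 ± 150 CPM in WT (n = 3), the cytolinker Plec at 2187 and 1818 CPM against 534 ± 157 CPM, and the kinase Rock1 at 284 and 267 CPM against 130.2 ± 15.3 CPM. The library of batch 8317 held 420.4, 294 and 95.6 CPM. Lower genes included Akna, an AT-hook factor, at 97.7 and 87.7 CPM against 352 ± 18.8 CPM, the isoleucyl-tRNA synthetase Iars at 270.4 and 272 CPM against 627 ± 70.6 CPM, and Caprin1, an RNA-binding protein of stress granules, at 288 and 298 CPM against 629 ± 72.7 CPM, with 348.5, 623 and 648 CPM in the library of batch 8317. These values compare 2 libraries with 3 and carry the open explanations given for this pattern.

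The exTreg Het libraries of batches 20190 and 20191 also held Cr2 at 8.15 and 26.0 CPM, H2-Ab1 at 98.0 and 71.0 CPM and H2-Eb1 at 93.4 and 93.3 CPM, against at most 5.28, 32.5 and 47.1 CPM in the other 8 in vivo exTreg libraries. The B cell receptor chain Cd79a held 1.59 and 3.45 CPM in them and at most 2.63 CPM in the others. The neutrophil genes S100a8 and S100a9 held 26.2 and 22.1 CPM in the Het exTreg library of batch 20086 and 12.3 and 4.29 CPM in the Het Treg library of the same batch. The Het Treg library of batch 23935 held 8.945 and 2.24 CPM, and the other in vivo libraries at most 2.67 and 1.47 CPM. The sort stained for CD19 and for the T cell receptor.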
